A study of Mus musculus with 4 samples.

How the data were processed

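RNA-seq was performed on 4 libraries of activated mouse CD4+ T cells, 2 from wild type and 2 from Setd2 knockout cells. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced on an Illumina HiSeq platform by a sequencing institute. Per the submitters' processing notes, the tools were Bowtie2 and RSEM and the genome builds GRCm38.p6 and mm10, and their versions and settings are not given in the sources used here. The deposited table held 18560 genes, each with an expected count per sample, which RSEM estimates by sharing reads that match more than one gene and which need not be whole. The deposited table also held an expression value per sample whose header does not state a unit. It was taken as FPKM (fragments scaled by gene length and library size), made by the authors, because the gene lengths it implies had a median ratio of 0.995 to annotated transcript lengths over 468 genes with a single transcript. The 4 columns of group averages were not used here. Of the gene IDs, 18420 (99.2%) matched the RefSeq gene table of GRCm38.p6, from which coordinates were taken, and 98.7% of genes were protein coding. The 13 mitochondrially encoded genes of the fixed quality list had no line in the table, so the mitochondrial share was not analysed here.

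Each library had between 17284613 and 20418766 counts, and between 15351 and 15890 genes were detected. The most abundant gene, Eef1a1, took at most 1.62% of the counts. No pair of libraries matched within sampling noise, with chi-square per degree of freedom between 29.7 and 161.5, so all 4 were kept as separate samples. Samples were grouped by genotype as the labels give it. The replicate numbers 1, 6, 9 and 12 are not shared between groups, so samples were not paired.

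Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr at its minimum count of 10, which left 12816, and scaled by TMM, with factors of 1, 1.056, 0.998 and 0.949. The knockout was compared with wild type by the quasi-likelihood F test of edgeR 4.0.16 with robust estimation (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0678, with 2 residual and 5.74 prior degrees of freedom. The SE of a log2 fold change was taken from the F statistic. Before the data were examined, 19 gene lists on T cell programmes, lipid metabolism and cell state were fixed, with 8 lists of cell type markers and 2 quality lists (mitochondrial and sex-linked genes). The 19 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19, and again with the correlation estimated from the data. With that estimate 0 of the 8 lists called up and 0 of the 3 called down were kept. This loss is not by itself a sign of correlated genes, since the estimated form rests on the 2 residual degrees of freedom. Few lists of any kind could pass it here. For the Th17 list the estimate was -0.039, below the preset, yet the unadjusted camera p went from 6.5e-06 to 0.04. It was also below the preset for the Th1 list (-0.044). Estimates far above the preset were found for the cholesterol (0.947), oxidative phosphorylation (0.912), glycolysis (0.773), naive (0.681) and fatty acid synthesis (0.401) lists. For these lists the camera p at the preset may be too small. Counts of list members were made over all genes and adjusted over the list alone.

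Named genes were chosen by a rule set before the data were examined. It took Setd2 and Lpcat4, up to 6 called genes of largest fold and 4 of smallest p in each direction (mean CPM of at least 5 in the higher group for the former, unnamed gene models left out), up to 2 called members of each list or, with none called, the 1 of smallest p, and the most abundant member of each marker list. Since 1 gene was called, most named genes are list members of smallest p. Agpat2, Lpcat1, Lpcat3, Id3, Cpa3, Hba-a2, Cd3g and all further members of the Th17, Th1, Treg, Tfh and naive lists were chosen after their values were seen. Some members of these lists are not reported here by name.

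The test was checked on simulated data for the same comparison, with 100 genes changed 2-fold and 100 changed 4-fold among 12816 genes. The changed genes were drawn from those with a mean count of at least 50. Genes were simulated independently, without the length trend of the real libraries. edgeR recovered 41% of the 2-fold and 91% of the 4-fold changes, and 18 of its 150 calls were genes simulated without a change. DESeq2 recovered 49% and 94%, with 24 such genes among 167 calls. For both tools unchanged genes made up a larger share of the calls than the threshold of 0.05. In the simulation a 2-fold difference was thus found less often than not, even at a mean count of at least 50. These rates need not hold for the real libraries.

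Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors or library size in place of TMM, no filter on low counts or a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), each library left out in turn, a 2-fold minimum, an adjusted p under 0.1, and fry in place of camera. Chosen after seeing the data were the removal of a loess trend on effective gene length or on GC content from each library and the newer dispersion method of edgeR. DESeq2 gave no adjusted p for 746 genes, which stayed missing. Tables were prepared and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.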

Results

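The data were gene-level RNA-seq counts from 4 libraries of mouse CD4+ T cells. Naive CD4+ T cells from C57BL/6 spleen had been activated with antibodies against CD3 and CD28, which gives Th0 cells, activated helper T cells not steered toward any effector type. In the group of 2 wild type libraries the replicates were numbered 1 and 6, and in the group of 2 Setd2 knockout libraries (Setd2 deleted with a Cre recombinase under Cd4 control) they were numbered 9 and 12. Setd2 is the methyltransferase that places trimethylation on lysine 36 of histone H3. The sources differ on how long the cells were stimulated, with 48 in the sample titles, 2 days in the series design text and 3 days in the treatment labels. Total counts were 19663302 and 18748194 in wild type replicates 1 and 6, and 17284613 and 20418766 in knockout replicates 9 and 12. Levels below are CPM (counts scaled to library size) after TMM scaling, and fold changes are knockout over wild type on the log2 scale with their standard error (SE). No label says whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

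The knockout itself was read first from Setd2 (gene 235626, GRCm38.p6 chromosome 9, 110532500 to 110618633). Setd2 stood at 157.2 and 174.5 CPM in the wild type libraries and at 127.2 and 112.9 CPM in the knockout libraries, a log2 fold change of -0.47 (SE 0.21) with an edgeR adjusted p of 0.421. Both knockout libraries lay below both wild type libraries, but the difference did not pass the test. A gene-level count adds reads from every exon, deleted or not, so it says little about the part that was removed. Log2 fold changes fell with gene length in this data set, from a median of 0.4 for genes with an effective length under 1 kb to -0.51 for genes over 8 kb. Among 510 genes of about the effective length of Setd2, 8507 bases, the median was -0.42 and 43.9% lay lower than Setd2. With a trend on length removed from each library, an alternative added after the data were seen, the log2 fold change of Setd2 was -0.05. The Setd2 counts were therefore not a check of the genotype labels.

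**Figure D1:**
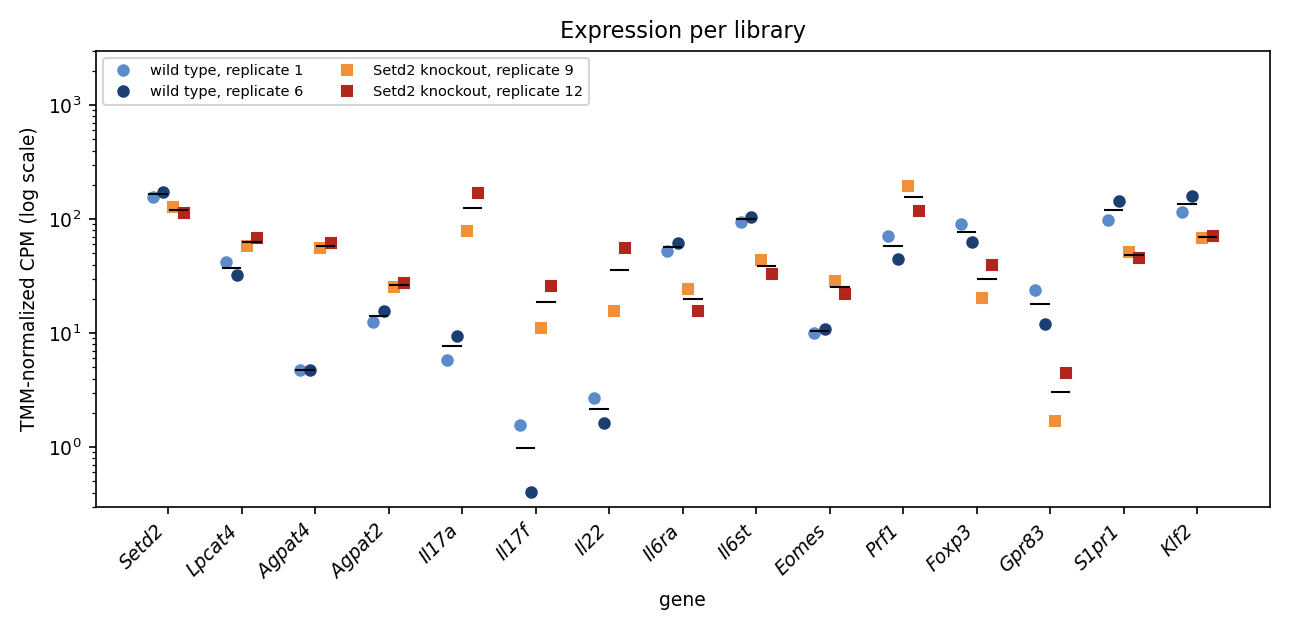
Expression of 15 genes in each of the 4 libraries, in TMM-normalized CPM on a log axis; circles are wild type and squares Setd2 knockout libraries, and short black lines are group means of 2 libraries. The Agpat4 values are 4.78 and 4.75 CPM in wild type and 55.3 and 61.2 CPM in knockout, while the Setd2 values of the groups lie close together.

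The series title names Lpcat4, which re-acylates lysophospholipids, as the target of interest. Lpcat4 (gene 99010, chromosome 2, 112239841 to 112247111) stood at 42.3 and 32.3 CPM in wild type and at 58.5 and 68.8 CPM in knockout libraries, a 1.71-fold difference (log2 0.77, SE 0.23) with an edgeR p of 0.0114 and an adjusted p of 0.386. A larger difference was found in another acyltransferase gene. Agpat4 (gene 68262, chromosome 17, 12118485 to 12219649), which acylates lysophosphatidic acid, rose 12.2-fold in knockout cells, from 4.77 ± 0.0192 to 58.2 ± 4.17 CPM (SD, n = 2 per group). Its log2 fold change was 3.61 (SE 0.23) and its edgeR adjusted p 0.00559, with both knockout libraries above both wild type libraries. The call was lost without knockout replicate 9 (log2 3.7, adjusted p 0.0825) and without knockout replicate 12 (3.54, adjusted p 0.288), fits in which the lone knockout library is assumed to vary like the wild type pair, and in limma-voom (adjusted p 0.0647). Of 30 tested genes of lysophospholipid acylation and phospholipid deacylation, Agpat4 was the 1 that passed, over all genes and when adjusted over the list alone. Agpat2 stood at 12.5 and 15.8 CPM against 25.2 and 27.5 CPM (adjusted p over the list alone 0.0927), whereas Lpcat3 (log2 0.37, SE 0.27) and Lpcat1 (-0.24, SE 0.27) differed by less than 2 SE. The list had a median log2 fold change of 0.13 and a camera adjusted p of 0.049 upward, with an adjusted p of 0.61 with an estimated correlation. Leaving out wild type replicate 1 (adjusted p 0.089), wild type replicate 6 (0.16) or knockout replicate 12 (0.23) also ended that call.

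Across all 12816 genes tested, edgeR called 1 gene higher (Agpat4) and 0 lower in knockout cells at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 799 higher and 734 lower, where 641 in all would pass by chance. Both knockout libraries lay above both wild type libraries for 3253 genes and below them for 3115, together 49.7% of the genes against 33.3% by chance for independent genes, which these are not, since one principal component with 56% of the variance ordered the 4 libraries. DESeq2 on the same counts called 88 genes higher and 97 lower, and limma-voom called 0 in either direction. Without wild type replicate 1 edgeR called 98 higher and 70 lower, without wild type replicate 6 it called 22 and 8, without knockout replicate 9 it called 1 and 0, and without knockout replicate 12 it called 0 and 0. At an adjusted p under 0.1 there were 6 higher and 2 lower. Besides Agpat4 they were Il17a, encoding the cytokine IL-17A, the interferon-inducible membrane protein genes Ifitm2 (2.14) and Ifitm3 (1.85), Phlda1 (2.21) and the granzyme gene Gzmc (1.94) among the higher, and P2rx7, an ATP-gated ion channel (-2.67), and Nmnat1, an enzyme of NAD synthesis (-2.43), among the lower. P2rx7 stood at 34.1 and 29.4 CPM against 4.29 and 5.68 CPM, and Nmnat1 at 34.7 and 41.0 CPM against 6.09 and 7.95 CPM, each with an edgeR adjusted p of 0.0671. These genes, except Il17a and Agpat4, were singled out after their values were seen.

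Several cytokine genes of the Th17 list were higher in both knockout libraries. Il17a stood at 5.8 and 9.51 CPM in wild type and at 79.4 and 169 CPM in knockout libraries, a 16.2-fold difference (log2 4.02, SE 0.45) with an edgeR adjusted p of 0.0671. Il17f (log2 4.23, SE 0.68) and Il22 (4.04, SE 0.63), which encode cytokines made by the same type of helper cell, were also higher in both knockout libraries, Il22 at 15.7 and 55.3 CPM against 2.7 and 1.62 CPM. Il21, another cytokine gene of the list, did not differ beyond its error (0.12, SE 0.29). Of 16 tested genes of the Th17 list, 8 were higher and 2 lower when adjusted over the list alone, against 0 over all genes tested in edgeR. DESeq2 called 5 higher and 2 lower over all genes, and 8 and 2 passed at an unadjusted edgeR p. Besides the 3 cytokines, those higher included Csf2, Tmem176a, Tmem176b and Il23r, a chain of the IL-23 receptor (log2 2.28, SE 0.49). Knockout replicate 12 held most of the rise for Csf2 (1.93 and 2.12 against 3.77 and 12.4 CPM) and Tmem176a (3 and 2.88 against 5.57 and 30.3 CPM). The same held for Tmem176b (4.68 and 5.51 against 7.72 and 27.7 CPM), but not for Il23r (0.916 and 1.26 against 6.03 and 4.59 CPM). The 2 lower were the chains of the IL-6 receptor, through which Th17 cells are induced, Il6ra (-1.5, SE 0.27) and Il6st (-1.36, SE 0.23), so the list did not move one way. Its median was 1.02, with a camera adjusted p of 3.1e-05 upward and an adjusted p of 0.61 with an estimated correlation. The median stayed positive with any single library left out, from 0.75 (without wild type replicate 6) to 1.35 (without wild type replicate 1). Over the list alone the counts of higher and lower genes were 4 and 2 without wild type replicate 1, 4 and 2 without wild type replicate 6, 7 and 3 without knockout replicate 9, and 5 and 2 without knockout replicate 12.

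Of 19 tested genes of the Th1 and cytotoxic list, 6 were higher and 2 lower when adjusted over the list alone, against 0 over all genes in edgeR. DESeq2 called 6 and 1 over all genes, and 7 and 3 passed at an unadjusted edgeR p. The 6 were Eomes, a transcription factor of cytotoxic T cells, Ifng, Gzmb, Prf1, Ccl3 and Fasl. Eomes stood at 10.02 and 10.87 CPM against 28.72 and 22.1 CPM (log2 1.28, SE 0.25) and Prf1, which encodes perforin, at 71.3 and 44.6 CPM against 194 and 117 CPM. The cytotoxic granule genes Gzma (log2 0.08) and Nkg7 (0.73, adjusted p over the list alone 0.0606) did not pass. The chemokine receptor gene Cxcr3 was among the lower, at 31.7 and 33.6 CPM against 15 and 21.6 CPM (log2 -0.83, SE 0.25). The camera adjusted p of the list was 0.033 upward, with an adjusted p of 0.61 with an estimated correlation. It was 0.12 with the length trend removed and 0.084 in limma-voom. The call was also lost without knockout replicate 9, where the list median was 0.11 against 0.18 with all libraries. No gene of the list was lower over the list alone without wild type replicate 6 or without knockout replicate 9. CD8 T cell genes differed in the same direction by less than 2 SE, with Cd8b1 at 140.6 and 183.4 CPM in wild type and 238.4 and 187.5 CPM in knockout libraries (log2 0.39, SE 0.24). Of the 8 CD8 and gamma-delta T cell markers 3 were measured, and they summed to 260.5 and 330.5 CPM against 432.6 and 323.7 CPM. Nearly all of that sum came from Cd8a and Cd8b1. Sox13, the third, was under 1 CPM in each library, so gamma-delta T cells were not assessed. Of 11 tested Th2 genes, 0 were higher and 1 lower when adjusted over the list alone, the IL-33 receptor gene Il1rl1 (-1.34, SE 0.33). That count of lower genes was 2 without wild type replicate 6 and 0 without any of the other 3 libraries in turn or with the length or GC trend removed. The median of the Th2 list was 0.4 (camera adjusted p 0.57), and it turned negative without wild type replicate 6 (-0.12) and without knockout replicate 12 (-0.42). The Th2 median was 1.09 without wild type replicate 1 and 0.84 without knockout replicate 9. With all libraries and an estimated correlation the camera adjusted p of the Th2 list was 0.91.

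Some genes of regulatory T cells and follicular helper cells were lower in the knockout libraries, and others were not. Of 18 tested Treg genes, 6 were lower and 1 higher when adjusted over the list alone and 0 over all genes in edgeR, with 4 lower in DESeq2. Foxp3, the lineage factor of regulatory T cells, stood at 90.3 and 63 CPM against 20.5 and 39.4 CPM (log2 -1.36, SE 0.35), and Gpr83 at 24.1 and 12.1 CPM against 1.68 and 4.44 CPM (-2.56, SE 0.53). Nt5e, Itgae, Izumo1r and Lrrc32 were the other 4 and Il1r2 the 1 higher. The list had 8 members with a positive log2 fold change and a median of -0.15. The camera adjusted p was 0.025 downward, with an adjusted p of 0.61 with an estimated correlation. Without knockout replicate 9 the Treg counts were 0 lower and 1 higher (camera adjusted p 0.6), without wild type replicate 6 or knockout replicate 12 there were 3 lower, and without wild type replicate 1 the camera adjusted p was 0.065. Of 13 tested Tfh genes, 3 were lower over the list alone (Il6ra, Slamf6 and Izumo1r) and 1 higher, Pdcd1, which encodes the inhibitory receptor PD-1 (log2 1.11, SE 0.21, 26.1 and 23.8 CPM against 57.4 and 50.7 CPM). The same 4 genes were called by DESeq2 over all genes and 0 by edgeR. The camera adjusted p of the Tfh list was 0.13, or 0.026 with the length trend removed and 0.61 with an estimated correlation.

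Of 22 tested genes of naive and quiescent T cells, 20 had a negative log2 fold change, with a median of -0.68. When adjusted over the list alone 6 were lower and 1 higher (the transcription factor gene Id3), against 0 over all genes in edgeR and 5 lower and 1 higher in DESeq2. S1pr1, the receptor with which T cells leave lymphoid organs, stood at 98.1 and 145 CPM against 51.6 and 45.3 CPM (log2 -1.32, SE 0.25), and Klf2, a transcription factor of quiescent T cells, at 116 and 158 CPM against 68.2 and 70.9 CPM (-0.98, SE 0.23). Lef1, Txnip and Satb1 were also among the 6. The camera adjusted p was 1.8e-07 downward, with an adjusted p of 0.61 with the estimated correlation, which was 0.681. The median stayed negative with any single library left out, from -0.41 (without wild type replicate 6) to -0.85 (without wild type replicate 1). The counts lower over the list alone were 14 without wild type replicate 1, 1 without wild type replicate 6, and 0 without either knockout replicate in turn. Of the 26 tested genes of early T cell activation 0 passed over all genes or over the list alone in edgeR, with 2 higher and 1 lower at an unadjusted p and 1 in DESeq2, the immediate early gene Egr1 (-1.31, SE 0.32).

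**Figure D2:**
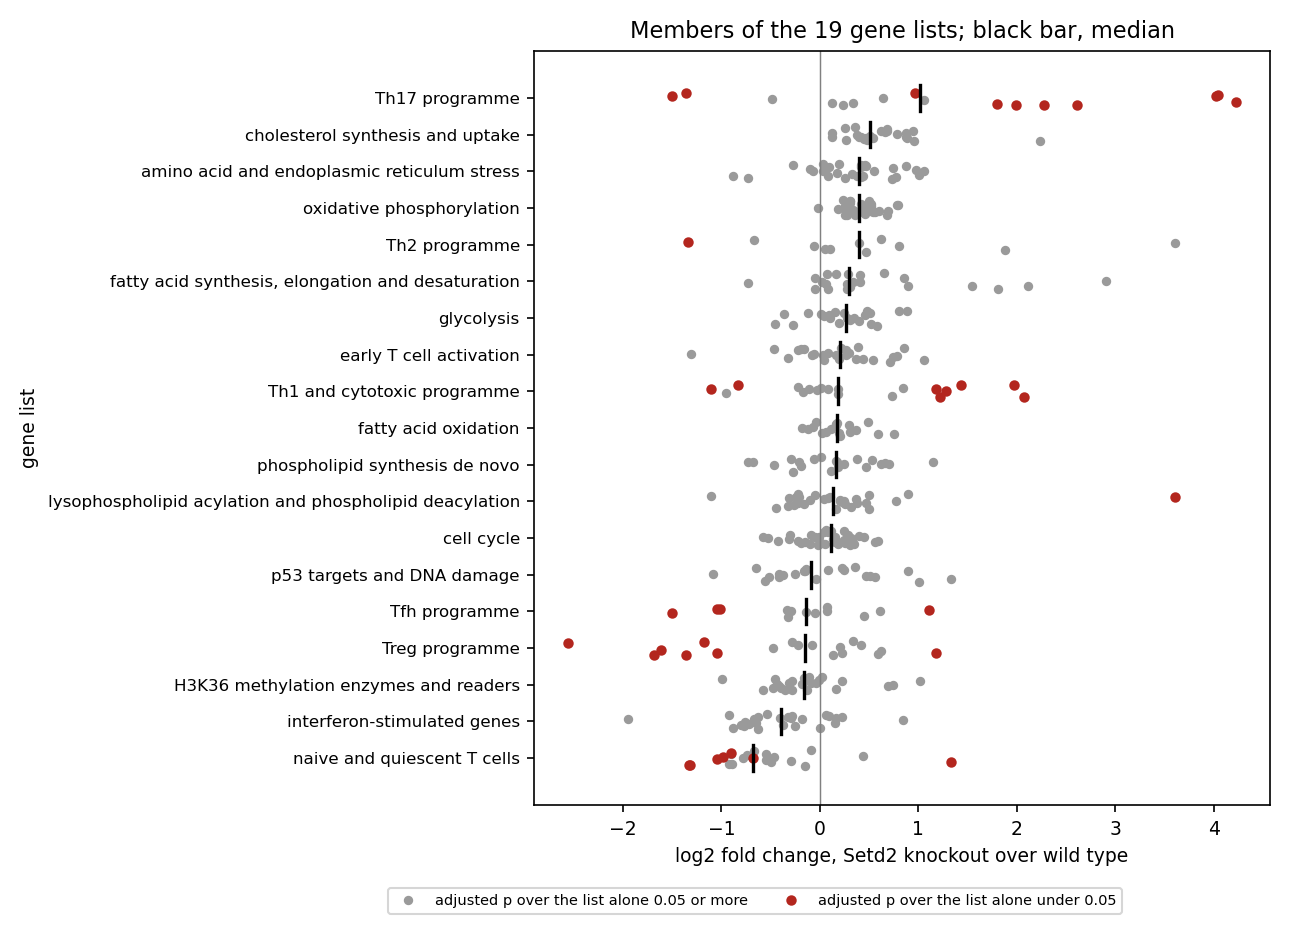
Log2 fold change of Setd2 knockout over wild type (horizontal axis) for each tested member of the 19 gene lists (vertical axis), ordered by the list's median, which is the black bar; points in red have an adjusted p under 0.05 over the list alone. The Th17 list has the highest median, 1.02, and the list of naive and quiescent T cells the lowest, -0.68.

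All 25 cholesterol synthesis and uptake genes had a positive log2 fold change (median 0.51), as had 30 of 31 oxidative phosphorylation genes (0.4), 19 of 22 genes of fatty acid synthesis, elongation and desaturation (0.3) and 18 of 22 glycolysis genes (0.26). Their camera adjusted p values were 5.5e-06, 2.5e-06, 8e-04 and 0.011, and with an estimated correlation the adjusted p values were 0.61, 0.61, 0.61 and 0.67. Those estimates were 0.947, 0.912, 0.401 and 0.773, against the preset of 0.01. No member of these 4 lists passed over all genes or over the list alone in edgeR, or over all genes in DESeq2, and 0, 5, 6 and 2 members were higher at an unadjusted edgeR p. Wild type replicate 6 was the lowest library in each list's summed CPM, and for cholesterol genes it stood at 1124 CPM against 2330 CPM in wild type replicate 1, and 2237 and 2817 CPM in the knockout libraries. The enzyme of sterol synthesis Msmo1 was also lowest in wild type replicate 6, at 70.7 and 34 CPM against 78.2 and 102 CPM (log2 0.78, SE 0.35). Without wild type replicate 6 the camera adjusted p was 0.21 for cholesterol genes, 0.061 for fatty acid synthesis and 0.46, in the downward direction, for glycolysis, and without knockout replicate 9 it was 0.057 for glycolysis. Without wild type replicate 1, 18 cholesterol, 6 fatty acid synthesis and 5 glycolysis genes were higher over the list alone. With the length trend removed the camera adjusted p of oxidative phosphorylation was 0.054 and its median 0.12. With a library left out, that median ran from 0.21 (without knockout replicate 12) to 0.6 (without wild type replicate 1). The cholesterol median ran from 0.11 (without wild type replicate 6) to 1.23 (without wild type replicate 1). The electron carrier gene Cycs (0.79, SE 0.29), the hexokinase gene Hk2 (0.88, SE 0.28) and the desaturase family gene Fads3 (2.91, SE 0.85, under 3 CPM in each library) had the smallest p of the lists they belong to.

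The list of amino acid and endoplasmic reticulum stress genes had a positive median (0.4, 23 of 28 positive, camera adjusted p 0.0087), with an adjusted p of 0.61 with an estimated correlation and 0.19 without knockout replicate 9. Its chaperone gene Hsp90b1 stood at 694 and 387 CPM against 806 and 1370 CPM (log2 1.01, SE 0.36). Over the 17 alternative settings the log2 fold change of Hsp90b1 ran from 0.58 to 1.49. The median of the stress list was 0.15 without knockout replicate 9. Interferon-stimulated genes had a negative median (-0.39, 20 of 26 below 0, camera adjusted p 0.0016), with an adjusted p of 0.61 with an estimated correlation and 0.33 without knockout replicate 9. Trim30a was the member with the smallest p, at 154 and 161 CPM against 94.2 and 86.4 CPM (-0.8, SE 0.21), and it was the 1 member called by DESeq2. In both lists 0 members passed over the list alone in edgeR, with 2 higher and 1 lower, and 1 higher and 5 lower, at an unadjusted p. Without wild type replicate 1 the stress list had 5 higher and 1 lower over the list alone and the interferon list 1 lower. The interferon median was -0.19 without knockout replicate 9 and -0.75 without knockout replicate 12. The remaining lists did not pass camera: fatty acid oxidation (median 0.17, adjusted p 0.073), phospholipid synthesis de novo (0.16, 0.48), early T cell activation (0.2, 0.13), cell cycle (0.11, 0.4), and H3K36 methylation enzymes and readers (-0.16, 0.085). For p53 targets and DNA damage the median was -0.09 while the mean was 0.04. Camera pointed up for them (adjusted p 0.89, or 0.97 with an estimated correlation). Camera called fatty acid oxidation upward without wild type replicate 6 or knockout replicate 9 (0.045 each), but its adjusted p was 0.26 without either other library in turn, 0.44 with the length trend removed and 0.63 with an estimated correlation. It called p53 targets upward without wild type replicate 6 (0.02). It called H3K36 enzymes downward without wild type replicate 6 (0.04) or knockout replicate 9 (0.02), but with the length trend removed their median was 0.01 and the adjusted p 0.71, and with an estimated correlation the adjusted p was 0.7. The members with the smallest p in these lists were Eci1 (0.75, SE 0.26), Etnk1 (-0.68, SE 0.21), Foxm1 (-0.53, SE 0.22), Ash1l (-0.99, SE 0.32) and Pmaip1 (1.01, SE 0.27), and none passed over all genes. With the length trend removed Eci1 was at 0.43, Etnk1 at -0.38 and Ash1l at -0.61, and Ash1l was at -1.53 without knockout replicate 9 and -0.58 without knockout replicate 12.

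Markers of other cells were followed in the same libraries. B cell markers summed to 967 and 722.6 CPM in wild type and to 843.3 and 1567 CPM in knockout libraries, and the most abundant, Cd74, stood at 366.5 and 298.1 CPM against 312.1 and 694.8 CPM. Knockout replicate 12, with the highest B cell sum, was also the library highest in Il17a and Il22. NK cell markers summed to 14.5, 22.56, 27.9 and 17.6 CPM in wild type replicates 1 and 6 and knockout replicates 9 and 12, and macrophage, monocyte and dendritic cell markers to 150, 176.3, 132.3 and 196.7 CPM. Sums in the same order were 12.77, 32.98, 20.88 and 14.77 CPM for neutrophil and mast cell markers, 9.156, 27.82, 8.296 and 12.55 CPM for erythroid and platelet markers, and 85.3, 120, 98.22 and 56.63 CPM for stromal and endothelial markers. Over its list alone the mast cell protease gene Cpa3 was higher (under 1 CPM in each library), and the hemoglobin genes Hbb-bs and Hba-a2 were lower, Hbb-bs at 3 and 10.4 CPM against 1.16 and 1.19 CPM. The log2 fold change of Hbb-bs was -2.5, and it was -1.35 without wild type replicate 6 (adjusted p 1) and -3.14 without wild type replicate 1 (adjusted p 0.0113). The Fc receptor chain gene Fcer1g (0.88, SE 0.4), the protease gene Ctss (-0.03, SE 0.3), the chemokine receptor gene Cxcr2 (-0.92, SE 0.66) and Pecam1 (-0.81, SE 0.31), the most abundant markers of 4 of these lists, did not pass. T cell identity genes summed to 5856, 5748, 5162 and 5697 CPM, with Thy1 higher at 781.4 and 608.2 CPM against 1105 and 1258 CPM (log2 0.77, SE 0.22, edgeR adjusted p 0.384) and Cd3g lower at 318 and 375 CPM against 222 and 240 CPM (-0.59, SE 0.21). Of the 14 tested, 11 had a negative log2 fold change and 3 a positive one. Both knockout libraries lay below both wild type libraries for 9 and above them for 1, against 3115 and 3253 of all 12816 genes. None of the 14 passed over the list alone. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were detected in all 4 libraries.

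Libraries of one genotype were not always closer to each other than to those of the other genotype. Pearson's correlation of log2(CPM + 1), across genes, which are not independent replicates, was 0.979 between the wild type libraries and 0.977 between the knockout libraries. It was highest, 0.984, between wild type replicate 1 and knockout replicate 9, and lowest, 0.945, between wild type replicate 6 and knockout replicate 12. The first principal component held 56% of the variance and placed wild type replicate 6 at -54.9, wild type replicate 1 at -7.9, knockout replicate 9 at 6.6 and knockout replicate 12 at 56.2. Long genes ran lower and short genes higher in knockout replicate 12 than in its own group partner, with a median log2 ratio of -0.62 for genes over 8 kb and 0.4 for genes under 1 kb.

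**Figure D3:**
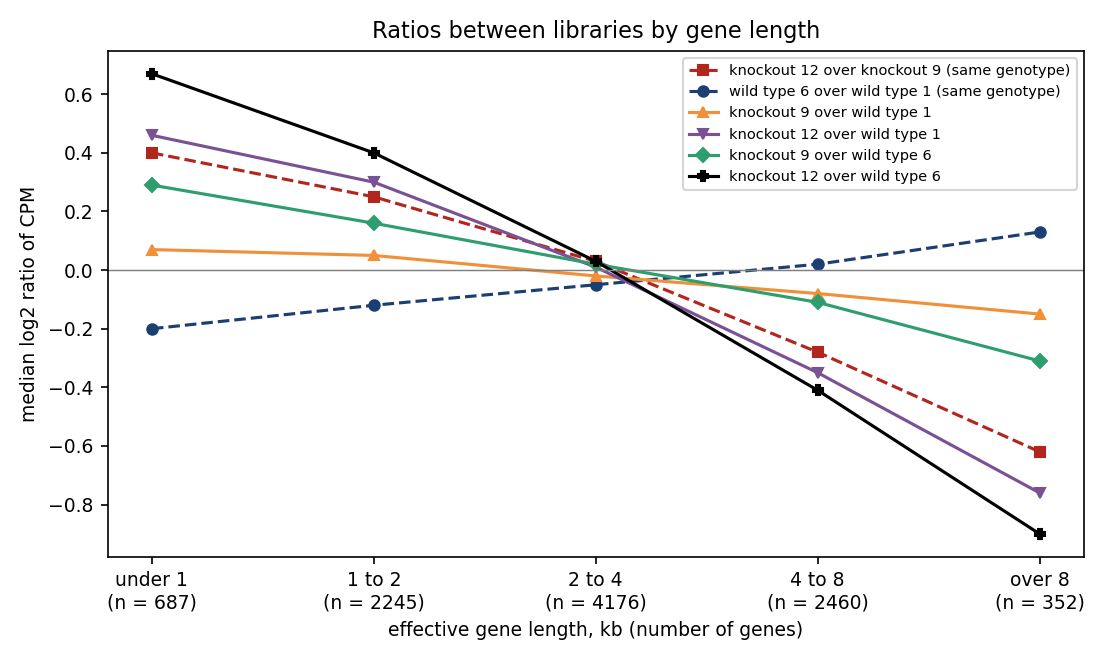
Median log2 ratio of CPM (vertical axis) between pairs of libraries for 9920 genes in 5 bins of effective gene length in kb (horizontal axis); dashed lines join libraries of one genotype and solid lines libraries of different genotypes. Knockout replicate 12 over knockout replicate 9 runs from 0.4 to -0.62, and knockout replicate 9 over wild type replicate 1 from 0.07 to -0.15.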

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

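Chosen after the data were seen were the removal of length and GC trends and the newer dispersion method of edgeR, and the other settings were fixed beforehand. The count of genes higher in knockout was 1, and of genes lower 0. They became 48 and 33 without a filter on low counts, 88 and 97 in DESeq2, 6 and 2 at an adjusted p under 0.1, and 3 and 2 with the newer dispersion method. Limma-voom called 0 higher. Leaving out one library gave 0 to 98 higher and 0 to 70 lower, and the 1 gene called without knockout replicate 9 was Cxcl3, named after its values were seen, not Agpat4. Of the 81 genes called without the filter, 80 were also called by DESeq2. The cause of these moves was not tested. Of the gene lists, 11 were called by camera, 0 with an estimated correlation and 0 by fry for one direction, whereas fry for either direction gave an adjusted p of 0.022 for the lysophospholipid, Treg and Tfh lists. The camera calls of the lysophospholipid, Th1 and Treg lists were lost in 13, 7 and 7 of 19 settings. Setd2 (-0.55 to -0.05) and Lpcat4 (0.59 to 0.98) kept their direction without passing in all 17 settings, and Agpat4 kept its direction in all 17 and its call in 14 of them. Direction reversed for the p53 list without a low-count filter (adjusted p 0.93) and with the length trend removed (0.77), and for Ctss with the GC trend removed (log2 0.01). With a library left out, the direction reversed at an adjusted p of 0.089 and 0.23 for p53, 0.46 for glycolysis, 0.061 and 0.087 for Th2 and 0.46 for cell cycle. Over all 4 such fits, reversed or not, the adjusted p was 0.02 to 0.24 (p53), 5.6e-07 to 0.46 (glycolysis), 0.012 to 0.087 (Th2) and 0.089 to 0.72 (cell cycle). Over the same fits the log2 fold change changed sign within -0.53 to 0.36 (Ctss), -1.83 to 0.19 (Cxcr2), -0.09 to 1.09 (Cd74) and -0.31 to 1.99 (Eif2s3y). Library size alone moved the median log2 fold change of all genes by -0.081 and voom by -0.08. No paired analysis was possible because the groups share no replicate number.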

Other observations

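The tests of a single library, of a Th17-type share, of a linked segment for Agpat4, of the length trend within one genotype and of the Ifitm pair counted once were chosen after the result was seen, and the others were written before their result was seen. The interferon-inducible genes Ifitm1, Ifitm2 and Ifitm3 are given as values, chosen after they were seen. None passed an adjusted p of 0.05 in the main edgeR test, whereas DESeq2 called Ifitm2 (adjusted p 2.55e-11) and Ifitm3 (1.88e-07). Ifitm2 stood at 16.6 and 20.9 CPM in wild type and 89.4 and 75.5 CPM in knockout libraries, and Ifitm3 at 11.2 and 12.7 CPM against 44.1 and 41.8 CPM, each with an edgeR adjusted p of 0.0671. Their neighbour Ifitm1 stood at 11.6 and 26.4 CPM against 58.2 and 37.4 CPM (adjusted p 0.393). These 3 genes are similar in sequence, and reads shared among them were assigned by the authors' counting, so the split between them is uncertain. Cytokine genes of the Th2 list, also chosen after their values were seen, varied widely within each genotype. Il24 was higher in both knockout libraries, at 4.88 and 0.759 CPM against 11.4 and 57.4 CPM (log2 3.61, edgeR adjusted p 0.413), whereas the groups overlapped for Il13, at 21.1 and 4.45 CPM against 15.0 and 79.4 CPM, and for Il10, at 43.6 and 12.6 CPM against 17.1 and 43.2 CPM. In each of the 3, wild type replicate 6 was the lowest library. The Y-linked gene Eif2s3y stood at 18.4 CPM in wild type replicate 1 and at 90.7, 85.5 and 60.8 CPM in wild type replicate 6 and knockout replicates 9 and 12, while Ddx3y stood at 66.3, 64.3, 63.9 and 35.2 CPM in that order.

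Log2 fold changes fell with gene length across 9920 genes (rho -0.5). Between the knockout libraries alone, Spearman's rho of the log2 ratio (replicate 12 over 9) with effective length was -0.58 across genes, so a trend of single libraries may account for it, and the same value of -0.58 argues against genotype as the whole cause. Removing a trend on GC content left a rho of -0.48, which argues against GC content. No library or RNA batch is given in the labels. A lesser length trend tied to genotype stays open, since knockout replicate 9 over wild type replicate 1 had a rho of -0.2. That value is no larger in size than the rho within wild type, 0.21 for replicate 6 over 1, so it is not a sign of genotype by itself. The other ratios of knockout over wild type also had a negative rho. It was -0.28 for replicate 9 over 6, -0.6 for replicate 12 over 1 and -0.53 for replicate 12 over 6.

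For the higher Il17a, Il17f and Il22 the small size of the length trend argues against gene length. Median log2 fold changes by gene length ran only from 0.4 to -0.51. The median of the 3 genes was 3.67 with the trend removed, which adds little, since so small a trend could hardly have changed it. The tables argue against knockout replicate 12 as the sole source, since the lowest log2 fold change of the 3 was 2.87 without it. A larger share of Th17-type cells in the knockout cultures stays open. The median of Ccr6, Il23r and Il1r1 was 1.06, between bounds of 2 (for a share) and 1 (against it) that were chosen after the result. The 3 genes were split, with Il23r at 2.28, Il1r1 at 1.06 and Ccr6 at 0.34. The median therefore cannot decide, since genes that other cells also express could move less than the cytokines under a share alone. Higher cytokine expression per cell upon loss of Setd2 is thus a hypothesis that cannot be told apart from a shift in cell types. The libraries are bulk cultures, and gamma-delta T cells were not assessed.

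For the 12.2-fold higher Agpat4, gene length is argued against by the small size of the length trend. Median log2 fold changes by gene length ran only from 0.4 to -0.51. The log2 fold change of 3.46 with the trend removed adds little, since so small a trend could hardly have changed it. A single library is argued against by a lowest value of 3.54 over the 4 fits that leave one library out, although 2 of these fits lost the call. A linked chromosomal segment stays open, since the 9 tested genes within 1 Mb had a median log2 fold change of -0.13 and such a segment need not move its other genes. That loss of Setd2 raises Agpat4 remains a hypothesis, found and tested on the same 4 libraries, and whether the effect is direct was not tested.

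The 60 genes with the smallest p held 5 (Utf1, Adam8, 5830411N06Rik, Ifitm2 and Ifitm3) within 2 Mb on chromosome 7, from 139943856 to 141010744, a number reached in a share of 8e-04 of 10000 random draws, or of 0.02 for a number of 4 with Ifitm2 and Ifitm3 counted once. The 17 other tested genes in that span had a median log2 fold change of 0.17. The 131 tested genes within 5 Mb of Setd2 had a median absolute log2 fold change of 0.29, at percentile 14 of 10000 random sets matched on expression, which argues against carry-over around the floxed allele that moves these genes as a set, while single neighbours stay open.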
